A study of Mus musculus with 8 samples.

How the data were processed

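The samples are 8 RNA-seq libraries of flow-sorted alveolar macrophages, 4 from Tfam-floxed mice without Cre (WT) and 4 from floxed mice with a CD11c-driven Cre (KO), all from mice of 3 weeks, and groups and replicate numbers come from the sample titles. Per the labels' protocols, lungs were digested with enzymes, CD11c-positive cells were enriched on magnetic columns and sorted on CD45, F4/80 and CD11c, RNA was treated with DNase, and libraries were made with a kit that keeps strand. The submitters' processing notes name CASAVA 1.8.2, cutadapt 1.7.1, RSEM 1.3.1, limma and the genome build GRCm38. The aligner, the annotation release and the counting setting for strand are not given in the sources used here.

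The deposited table holds 1 normalised signal value per gene and library, made by the authors and not raw read numbers. Its form was read from the values. Every value is an odd multiple of the smallest in its column, which is what a whole read number plus 0.5, divided by a scaled library size and put on a per-million scale, gives, as in the linear form of the values that limma's voom makes. Read numbers came out whole for 100% of the values in each column at a tolerance of 0.01. The column sums differ from those of a plain per-million scale by a library factor, which was 1.03 ± 0.00728 in WT and 0.969 ± 0.00642 in KO (SD, n = 4). All 12367 rows exceed 1 on the per-million scale of reads in at least 3 libraries, so that genes under this level were not analysed here, and the sum of reads over the rows is a lower limit of the depth of a library. These read numbers served for depth, floors, shares of reads and the voom weights of 1 alternative. They were not used in the test behind the reported values.

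Values were tested as log2(value + 1) for genes with a value of at least 1 in at least 4 libraries, with limma 3.58.1 in R 4.3.3 (linear model, moderated variances with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). The filter left out 204 rows. Shares of reads, depths and Tfam were also tested with two-sided exact permutation tests, whose smallest p for 4 against 4 is 0.0286. The same read offset of 0.5 is already inside the deposited values, so that the pseudocount of 1 adds to it. The steps were tested on simulated data for this comparison with 11946 genes: 89.2% of changes of 0.5 log2, 100% of changes of 1 and 100% of changes of 2 were recovered, 18 of 233 calls were false (7.73%), and 0 null lists and the 1 planted list were called. The simulated genes were drawn independently, with 1 dispersion (0.00393), no pairing of libraries and few changed genes. These rates therefore need not hold for the data, and the list result cannot judge a preset correlation between genes.

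There were 28 gene lists and 12 marker lists, of which 38 had at least 3 measured members. For each list, members called higher or lower over all genes and adjusted over the list alone were counted, and camera was run with a preset correlation of 0.01 and with an estimated correlation, with adjustment over the 38 lists. Over all 12163 tested genes 38.7% were called, 2279 higher and 2429 lower, which is the background for these counts. With the preset correlation 9 lists were called, 6 up and 3 down, and with the estimated correlation 0 were called by camera, the lowest adjusted p being 0.315. Fry, which tests whether the genes of a list move and does not compare them with other genes, called 16 lists in 1 direction and 33 in either direction. The lists, the tests, the filter and the rule for named genes were set before the data were examined. The rule took Tfam, then the 12 highest and 12 lowest fold changes among called genes with above-median expression and no overlap between the groups, passing over predicted genes, then up to 4 members of each list by p. In the report, Trib3, Mthfd2, Gdf15, Kif11, Mcm4, Car4, Itgax, Ear2, Ear6, Hk2, Ldha, Atp6v1a, Wipi1, Map1lc3b, Gpx1, Hmox1, Cd36, Msr1, Nlrp3, H2-Aa, C1qb, mt-Co3, mt-Nd3, mt-Nd4l, Xist and Ddx3y lie outside this rule and were chosen after their values were seen. The alternatives were not run for these genes one by one. Some genes are not reported here, and the search for libraries that lie far from their group leaves them out.

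Samples of the 2 groups share replicate numbers. Deviations from the group means correlated at 0.36, 0.29, 0.39 and 0.43 between same-numbered libraries, against -0.37 to 0.092 for other pairs, and 8 of 8 libraries correlated best with their own number. The pairing is thus read from the data, since the labels do not say what a number marks, and a fit with the number as a block was run beside the unblocked one. Other alternatives were no filter, a minimum of 8, pseudocounts of 0.25 and 5, quantile normalisation, median centring, no variance trend, library quality weights, thresholds of adjusted p 0.01 and of 1 log2 unit, and leaving out each library. Values without a further pseudocount, voom weights and leaving out both replicate-4 libraries were added after seeing the data. A count-based test was planned for raw read numbers only and was not run. The read numbers here were inferred from the spacing of the values, few of which lie near 0 reads, and were not taken as certain enough for it. The voom weights rest on the same inferred numbers.

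Gene positions and lengths came from GENCODE M21, of the same build as the processing notes, in which 12362 of 12367 gene identifiers were found. The table gives no symbol for 13 rows, and 10 rows share a symbol with another row. Nuclear copies of mitochondrial genes were found as genes that share words of 31 bases with a mitochondrial mRNA. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.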

Results

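Polyadenylated RNA was sequenced from alveolar macrophages, the macrophages that live in the air spaces of the lung, taken from untreated mice at 3 weeks of age. The cells were flow-sorted as CD45+ F4/80+ CD11c+ cells from 2 genotypes. The control mice carried floxed alleles of Tfam (called WT below). The experimental mice carried the same alleles with a Cre recombinase driven by CD11c (called KO below). No group carried the Cre without floxed Tfam, so effects of the Cre itself cannot be told apart from loss of Tfam. Tfam encodes the mitochondrial transcription factor that packages mitochondrial DNA and is needed for its maintenance and transcription. Each genotype had 4 libraries, and each library was a pool of cells from 3 to 5 male and/or female mice, so that the replicates are different pools of animals. The series asks how oxidative phosphorylation acts on macrophages in tissue, and the design holds 1 comparison, KO against WT.

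The spacing of the deposited values gives 24776683 to 29161957 reads in the listed genes per WT library and 20243772 to 30263201 per KO library. These depths did not differ by a two-sided exact permutation test (p = 0.343). At this depth 3 reads correspond to a value of 0.1 to 0.152, a floor that covers counting error only. Values are given throughout on a normalised per-million-reads scale, mean ± SD over 4 pools, and fold changes are on the log2(value + 1) scale, which understates the change of low genes. The pools differed in sex mix. The X-inactivation transcript Xist lay between 64.6 and 183 in WT and between 73.7 and 204 in KO. The Y-linked Ddx3y lay between 45 and 106 in WT and between 42.7 and 113 in KO. Same-numbered pools differed too: Xist was 66.3, 183, 64.6 and 147 in WT replicates 1 to 4. It was 204, 148, 140 and 73.7 in KO replicates 1 to 4. The 20 most abundant genes took 11.8% ± 0.158 of the reads in the listed genes in WT and 15.4% ± 0.214 in KO, and a two-sided exact permutation test gave p = 0.0286, the smallest that 4 against 4 libraries allow. The first principal component held 63.8% of the variance and separated the genotypes. The second held 12.8% and set WT replicate 4 and KO replicate 4 apart from the other libraries, at 25.6 and 14.1.

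Tfam itself was lower in every KO library. The gene (ENSMUSG00000003923, build GRCm38, chromosome 10, 71225464 to 71238280) had values of 26.1 to 35.2 in the WT pools and 3.52 to 5.08 in the KO pools. Means were 30.3 ± 3.72 in WT and 4.35 ± 0.648 in KO, a log2 fold change of -2.55 (SE 0.117, limma adjusted p = 1.02e-06). The exact two-sided permutation test gave p = 0.0286. Gene totals do not separate the exons, so that the deleted part of the gene was not read apart from the rest.

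All 13 mRNAs that mitochondrial DNA encodes fell in KO, with a median log2 fold change of -3.76. Mt-Co1, a core subunit of complex IV, went from 5262 ± 968 to 393 ± 91. Mt-Cytb of complex III went from 1609 ± 330 to 112 ± 25.8 (log2 fold change -3.84, SE 0.183, limma adjusted p = 1.14e-06), and mt-Nd5 of complex I from 874 ± 195 to 52.4 ± 11.4 (log2 fold change -4.04). Of the reads in the listed genes, the share assigned to mitochondrial genes, without their nuclear copies, was 1.37% ± 0.263 in WT and 0.102% ± 0.0226 in KO, with an exact two-sided permutation p of 0.0286. Both mitochondrial ribosomal RNAs fell too, mt-Rnr2 by 2.14 and mt-Rnr1 by 1.75 on the log2 scale. Poly(A) selection captures ribosomal RNA incompletely, so these 2 values describe the captured part.

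**Figure D1:**
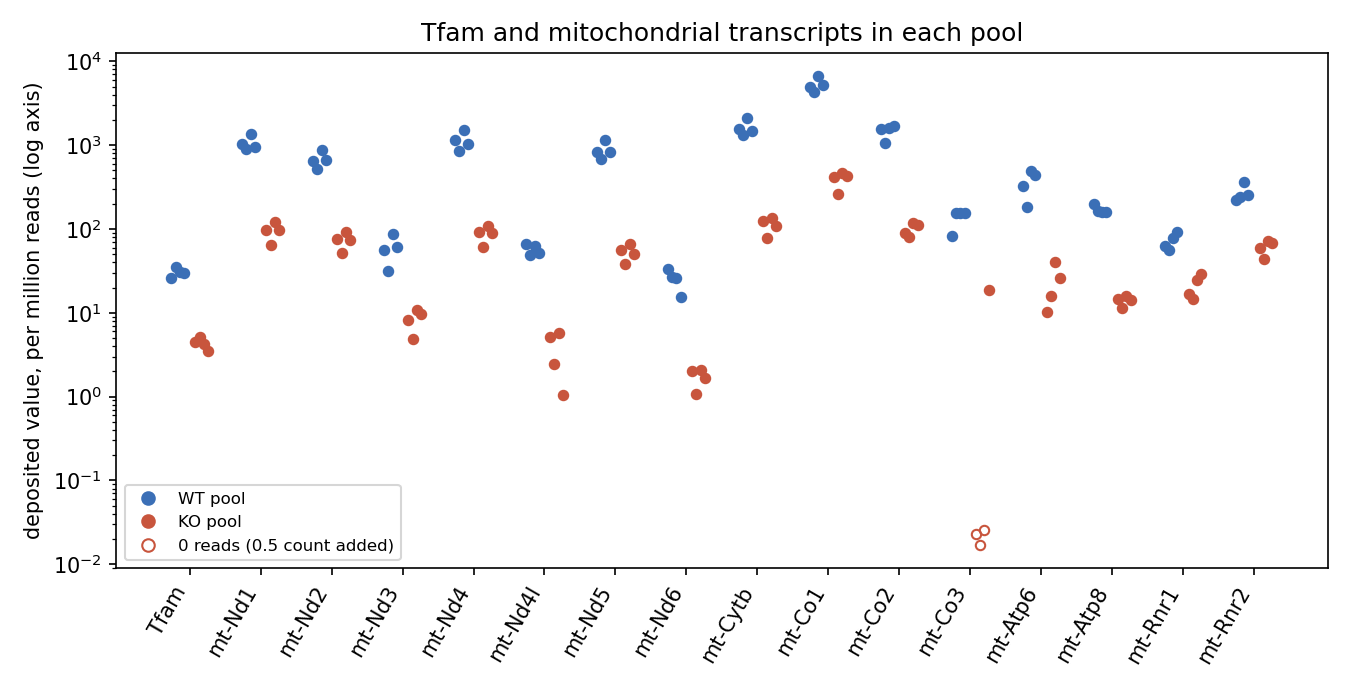
Values of Tfam, the 13 mitochondrial mRNAs and the 2 mitochondrial rRNAs in each pool (log axis, normalised per-million-reads scale; blue points are the 4 WT pools and red points the 4 KO pools). For every transcript drawn, each KO pool lies under each WT pool, and open points mark the 3 KO pools in which mt-Co3 was listed at 0 reads.

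The mRNA list was called by camera with a preset correlation (adjusted p = 4.89e-13), and its adjusted p was 0.497 with an estimated correlation. All 13 were also called when adjusted over the list alone. Mt-Co3, mt-Co2, mt-Atp6, mt-Nd3, mt-Nd4 and mt-Nd4l share most of their sequence with unprocessed pseudogenes on chromosome 1 that are in the table as genes of their own, so their single values are uncertain. Mt-Co3 was listed at 0 reads in KO replicates 1, 2 and 3 and at 18.8 in KO replicate 4, against 83.5 to 156 in WT. After the values of each mRNA were summed with those of its copies, the log2 fold change of mt-Co3 was -3.88 and those of the other 12 lay between -4.04 and -3.2.

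Nuclear-encoded genes of oxidative phosphorylation, which include the partners of these proteins and complex II, which has no mitochondrially encoded subunit, moved little. Of 76 measured nuclear genes for complexes I to IV and the ATP synthase, 17 rose, 1 fell and 58 did not pass the test, with a median log2 fold change of 0.0797 and a range of -0.26 to 0.716. The complex I accessory subunit Ndufa6 rose from 41.5 ± 3.2 to 69.1 ± 8.85, and Cox7a2l, a factor in supercomplex assembly, from 188 ± 10.9 to 279 ± 18.1 (log2 fold change 0.57, limma adjusted p = 0.000101). By list, 8 of 36 complex I genes, 1 of 4 complex II genes, 2 of 9 complex III genes and 5 of 12 complex IV genes rose and none of these fell, while in the ATP synthase 1 of 15 rose and 1 fell. Adjusted over the list alone, the risen members numbered 3, 1, 1, 5 and 1 in the same order. Camera called none of the 5 lists. Complex I was closest at an adjusted p of 0.0543, and passed under quantile normalisation (0.0214), median centring (0.0335) and without KO replicate 2 (0.0144), WT replicate 1 (0.0296) or WT replicate 2 (0.0114). Complex IV passed without KO replicate 2 (0.0498). The count of 8 in complex I was 13 with the replicate number as a block, 4 without KO replicate 1 or WT replicate 3, 3 without KO replicate 3, and 5 without KO replicate 4 or WT replicate 4. The risen gene of complex II was not called without KO replicate 1, 2 or 3 (count 0), and complex III had 1 in place of 2 without any single library but KO replicate 4. In the ATP synthase the fallen gene was not called without KO replicate 2 or 3 or WT replicate 1, 2 or 3 (count 0), 2 fell under quantile normalisation, and 2 rose without WT replicate 2 and under median centring.

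Among 20 genes of mitochondrial DNA maintenance and transcription, 2 rose and 4 fell (1 and 4 when adjusted over the list alone), and 1 rose without any single library but WT replicate 4. Tfb2m, a transcription factor that works with Tfam at mitochondrial promoters, fell from 33.1 ± 1.81 to 24.4 ± 1.35, and the coactivator Ppargc1b fell from 11.3 ± 1.63 to 7 ± 1.15. The median of this list was 0.0554, its mean -0.0161, and camera and fry gave opposite signs, with a camera adjusted p of 0.968. Of 77 genes of mitochondrial ribosomal proteins 11 rose and 3 fell (8 and 1 over the list alone). In this list 1 was lower without KO replicate 2 or 3 or WT replicate 2. Of 19 genes of the TCA cycle 3 rose and 1 fell (2 and 1 over the list alone). The TCA counts were 6 up and 3 down under the replicate block. They were 6 up without KO replicate 4 and 2 down without WT replicate 4. Neither list was called by camera (adjusted p = 0.206 and 0.572).

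Genes of the stress response driven by the transcription factor ATF4, together with one-carbon metabolism, rose as a group: 25 of 34 measured members rose and 0 fell (27 and 0 when adjusted over the list alone), with a median log2 fold change of 0.89. Asparagine synthetase, Asns, rose from 10.6 ± 2.91 to 113 ± 36.2 (log2 fold change 3.26, SE 0.253, limma adjusted p = 1.38e-05). The pseudokinase Trib3 rose from 2.33 ± 0.823 to 48.9 ± 25.5 and the mitochondrial folate enzyme Mthfd2 from 22.9 ± 5.42 to 143 ± 47.9. The cystine transporter Slc7a11 rose from 25.1 ± 8.85 to 184 ± 47.3, the secreted stress factor Gdf15 from 21.5 ± 8.93 to 90.4 ± 17.1, and Atf5 from 31.7 ± 6.08 to 138 ± 13. The list was called by camera (adjusted p = 2.62e-10), and the adjusted p was 0.597 with an estimated correlation. Without WT replicate 4, 1 member was lower. KO replicate 4 had the lowest value of Asns, at 63.4 against 109 to 143 in the other KO pools.

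Chaperones and proteases of the mitochondrial unfolded protein response rose in 6 of 11 members, with 0 lower (the same 6 over the list alone). Hspa9, the mitochondrial Hsp70, went from 325 ± 7.22 to 717 ± 136, and its cochaperone Dnaja3 from 42.6 ± 4.35 to 69.2 ± 5.89. Camera gave an adjusted p of 0.0142, and 0.597 with an estimated correlation. In the list of NRF2 targets and antioxidant defence 15 of 32 rose and 6 fell, with the same counts over the list alone. The glutathione transferase Gstm1 rose from 171 ± 8.68 to 526 ± 21.6 and haem oxygenase Hmox1 from 153 ± 10.7 to 329 ± 72.7, while the peroxidase Gpx1 fell from 494 ± 28.8 to 337 ± 44.3. Ferritin heavy chain, Fth1, was 5208 ± 165 in WT and 11931 ± 625 in KO, a call that quantile normalisation ended (adjusted p = 0.346). Camera gave 0.0047 for this list, and an adjusted p of 0.753 with an estimated correlation. Its 6 lower members were 2 without KO replicate 1 or 3 or WT replicate 2, and 3 without KO replicate 2 or WT replicate 1.

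All 42 measured genes of the cell cycle fell in KO, with a median log2 fold change of -1.38. The proliferation marker Mki67 fell from 223 ± 44 to 67.4 ± 9.25, topoisomerase Top2a from 158 ± 31.6 to 41.7 ± 9.16, the mitotic kinesin Kif11 from 48.9 ± 11.8 to 12.9 ± 2.28 and the replication helicase subunit Mcm4 from 92.7 ± 11.6 to 41.3 ± 5.09. Over the list alone the count was also 42. Camera called the list (adjusted p = 2.71e-19), with an adjusted p of 0.597 with an estimated correlation. Among 19 targets of p53 and apoptosis genes 10 rose and 3 fell (11 and 4 over the list alone, and 6 down under the replicate block). Zmat3 rose from 24.9 ± 1.41 to 58.8 ± 6.98 and Mdm2 from 68.5 ± 4.99 to 100.01 ± 6.22. Camera did not call this list (adjusted p = 0.114), while fry gave an upward adjusted p of 0.00278.

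All 75 measured genes of cytosolic ribosomal proteins rose, by a median of 0.74 on the log2 scale. Over the list alone the count was also 75. Rps19 rose from 228 ± 13.6 to 463 ± 28.9, Rpl14 from 368 ± 19.9 to 723 ± 45, and Rpl12 from 38.7 ± 3.09 to 91.8 ± 7.56. Camera called the list (adjusted p = 1.2e-35), and the adjusted p was 0.597 with an estimated correlation. Many of these genes have processed pseudogenes, between which the counting can split reads.

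**Figure D2:**
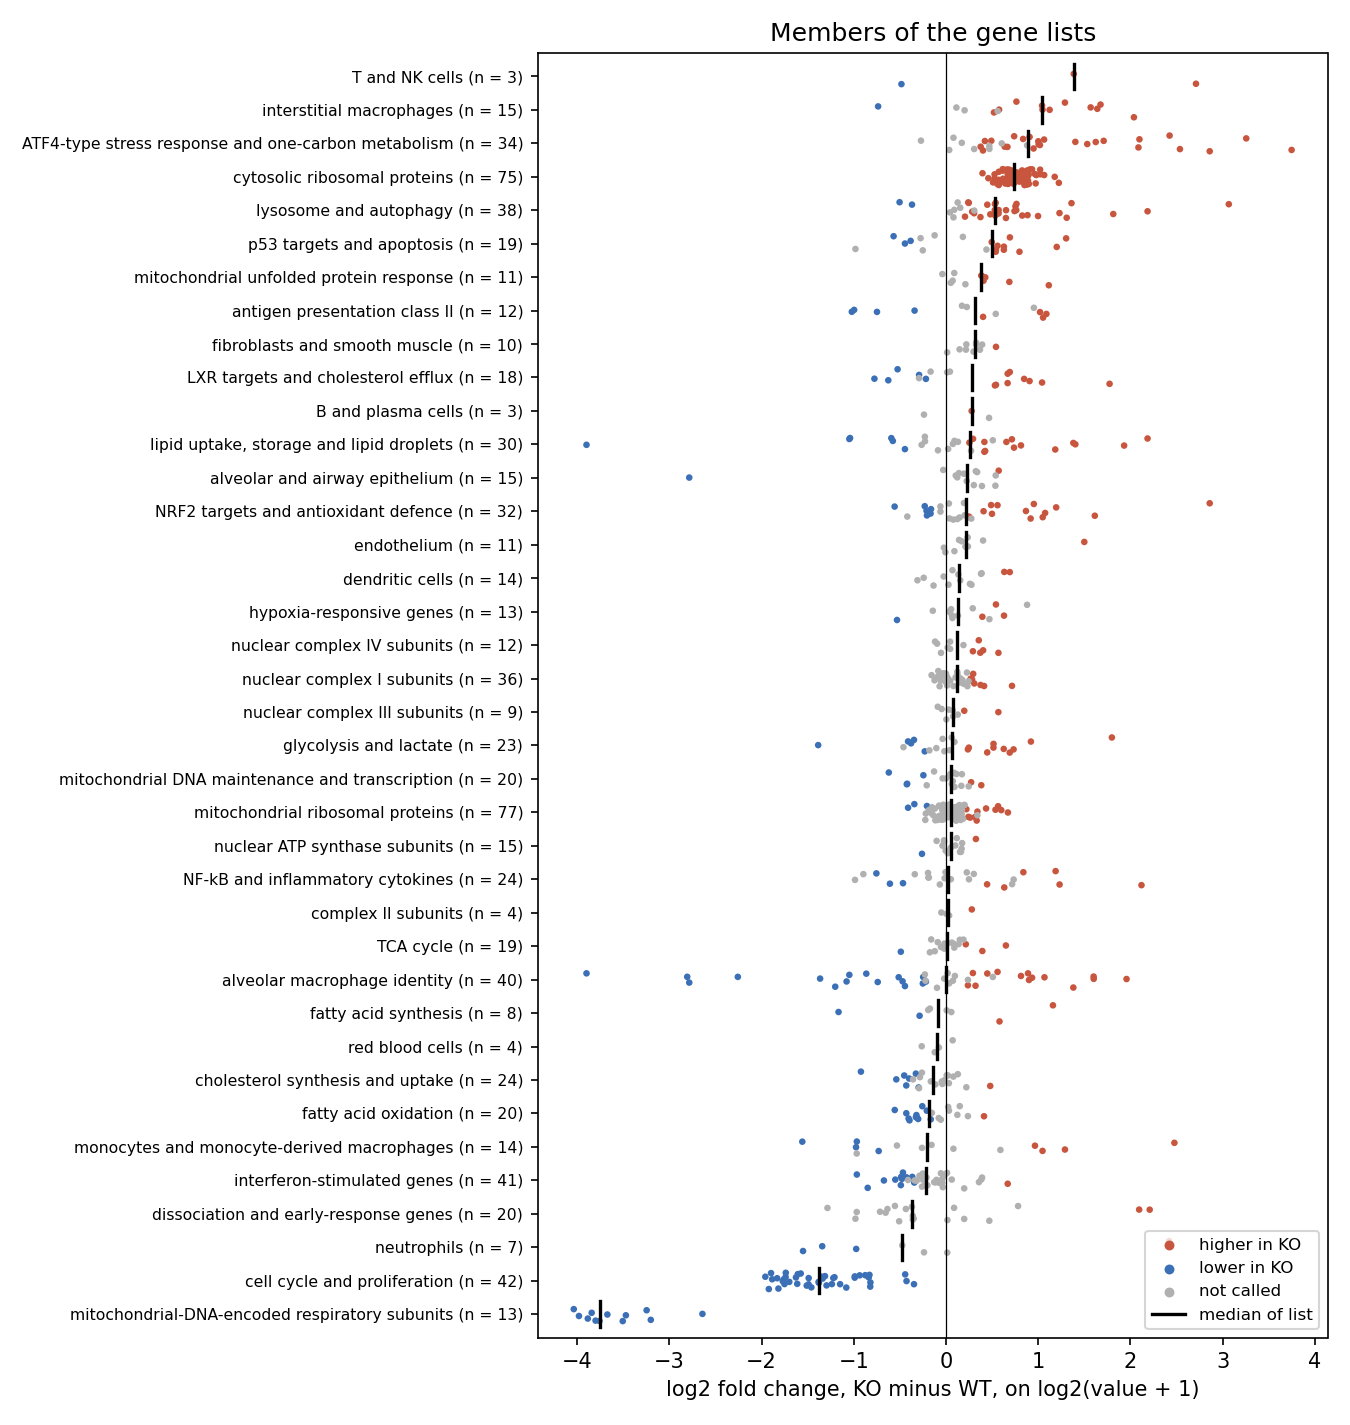
Log2 fold changes, KO minus WT, of the members of each list with at least 3 measured genes (red, higher; blue, lower; grey, not called; black line, median; mt-Co3 is counted but not drawn). The cell-cycle and mitochondrial mRNA lists lie wholly under 0 and the cytosolic ribosomal proteins wholly above it, while alveolar macrophage identity genes spread to both sides.

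Lysosome and autophagy genes rose in 30 of 38 members and fell in 2 (33 and 2 over the list alone), with a median log2 fold change of 0.54. The tetraspanin Cd63 rose from 59.3 ± 5.93 to 504 ± 42.8 (log2 fold change 3.07, SE 0.0857, limma adjusted p = 1.23e-07), the glycoprotein Gpnmb from 401 ± 78.5 to 1805 ± 185, the protease Ctsl from 239 ± 7.05 to 597 ± 63.3 and the proton pump subunit Atp6v1a from 289 ± 18.6 to 533 ± 22.6. The 2 that fell were Wipi1 and Map1lc3b, both of autophagosome formation. Camera gave an adjusted p of 3.8e-15, and 0.315 with an estimated correlation.

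Genes that mark alveolar macrophages moved both ways: 14 of 40 rose, 16 fell and 10 did not pass the test (15 and 16 over the list alone). The fatty acid binding protein Fabp1 fell from 180 ± 16.1 to 11.2 ± 2.5 (log2 fold change -3.90, SE 0.129, limma adjusted p = 1.55e-07). The lectin Siglecf fell from 501 ± 37.6 to 194 ± 20.9, the ribonuclease Ear1 from 845 ± 112 to 123 ± 39.3 and the adhesion molecule Epcam from 19.5 ± 1.77 to 2.05 ± 0.816. In the other direction, the protease Ctsk rose from 348 ± 24.8 to 1055 ± 43.9, the chemokine Ccl6 from 4202 ± 182 to 12788 ± 1172, the carbonic anhydrase Car4 from 723 ± 122 to 1336 ± 190, and Itgax, which encodes the CD11c of the sort gate and whose promoter drives the Cre, from 1094 ± 48.6 to 2050 ± 202. The median of the list was -0.00045, its mean was -0.169 and camera gave an adjusted p of 0.816, while fry gave a downward adjusted p of 0.0341. Ear1, Ear2 and Ear6 belong to a family of similar genes, between which reads can be shared.

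**Figure D3:**
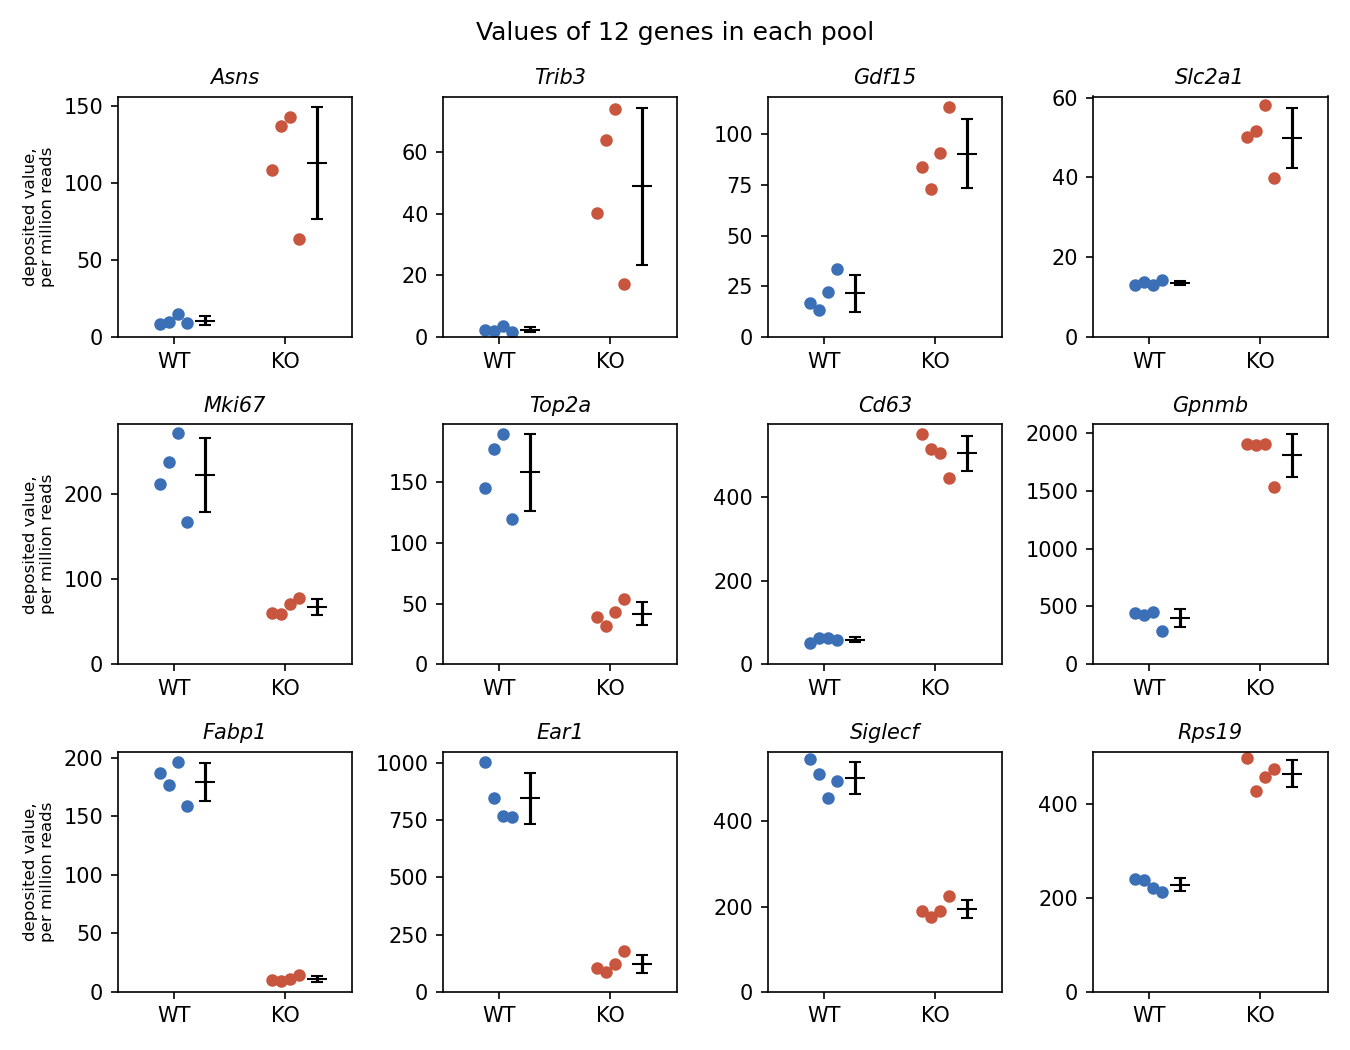
Values of 12 genes in each pool (normalised per-million-reads scale, axes from 0; black bars show mean and SD of 4 pools). In all 12 panels the KO pools and WT pools do not overlap, as for Mki67 at 223 in WT and 67.4 in KO on average, and KO replicate 4 is the lowest KO pool for Asns and Trib3.

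In glucose metabolism 10 of 23 genes of glycolysis and lactate rose and 5 fell, with the same counts over the list alone. The glucose transporter Slc2a1 rose from 13.5 ± 0.541 to 49.9 ± 7.47 and hexokinase Hk2 from 34.7 ± 4.5 to 66.5 ± 7.42, while Pdk4, which restrains pyruvate oxidation, fell by 1.39 on the log2 scale and lactate dehydrogenase Ldha from 485 ± 25.1 to 414 ± 30.9. Camera gave an adjusted p of 0.249 and fry an upward adjusted p of 0.0402. Of 13 hypoxia-responsive genes 3 rose and 1, Bnip3, fell (5 up and 2 down under the replicate block, 2 down without KO replicate 4 or WT replicate 3 and under quantile normalisation; adjusted p = 0.343 by camera and 0.00374, upward, by fry). The same 3 and 1 were called over the list alone.

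Lipid genes were split. In fatty acid oxidation 11 of 20 fell and 1 rose (11 and 1 over the list alone), among them the carnitine transferase Cpt1a, from 524 ± 31.9 to 356 ± 14.5. This list stood at a camera adjusted p of 0.0543, and passed without KO replicate 1 (0.0284), without WT replicate 4 (0.00713) and without both replicate-4 libraries (0.0368). Its 11 lower members were 7 without KO replicate 2 or 4 or without WT replicate 1, 2 or 3, and 2 members rose without KO replicate 4 and under the replicate block. In lipid uptake and storage 14 of 30 rose and 6 fell (15 and 8 over the list alone; camera adjusted p = 0.0992, fry adjusted p = 0.0381, upward). The scavenger receptors Cd36 and Msr1 rose from 734 ± 129 to 1661 ± 211 and from 15.3 ± 3.82 to 61.6 ± 14.9, and the lipid droplet protein Cidec fell from 414 ± 42.9 to 200 ± 17.5. Among cholesterol synthesis and uptake genes 7 of 24 fell and 1 rose (7 and 1 over the list alone). That list had a camera adjusted p of 0.114, against 0.00494 with 12 lower members without KO replicate 4, and 0.00989 without both replicate-4 libraries. Under the replicate block 11 members were lower and 2 higher. Of 18 LXR targets and cholesterol efflux genes 9 rose and 5 fell (9 and 6 over the list alone; camera adjusted p = 0.269, fry adjusted p = 0.00491, upward), and of 8 fatty acid synthesis genes 2 rose and 2 fell, as over the list alone, with 4 lower under the block and 1 lower without KO replicate 3 (adjusted p = 0.761).

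Interferon-stimulated genes fell in 11 of 41 members and rose in 1, Bst2, with the same counts over the list alone. Over all 12163 tested genes 38.7% were called, 2429 of them lower. The guanylate binding protein Gbp7 fell from 81.6 ± 8.76 to 50.7 ± 2.97. Camera gave an adjusted p of 0.0363, and 0.753 with an estimated correlation. The call was lost without KO replicate 3 (adjusted p = 0.0627) and without WT replicate 3 (adjusted p = 0.0937), where 2 and 3 members were higher. In the list of NF-kB targets and inflammatory cytokines 6 of 24 rose and 3 fell, as over the list alone, and 8 fell under the replicate block and 1 without WT replicate 3 (camera adjusted p = 0.572). The chemokine Ccl3 rose from 25.7 ± 14.1 to 102 ± 16.8 and the inflammasome sensor Nlrp3 fell from 103 ± 28 to 59.4 ± 8.48. Of 12 genes of class II antigen presentation 4 rose and 4 fell (5 and 4 over the list alone; camera adjusted p = 0.758). H2-DMa fell from 191 ± 28.8 to 96.3 ± 29. H2-Aa was at 104 ± 29.1 in WT and 243 ± 131 in KO (adjusted p = 0.0385). The 4 that rose numbered 0 without KO replicate 1, and 1 without KO replicate 3 or 4 or without WT replicate 2, 3 or 4. The median of the class II list was 0.31 while fry gave a downward sign.

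Markers of other cells that the gate or free RNA could bring in were counted the same way. Interstitial macrophage markers were higher: 11 of 15 rose and 1, Selenop, fell (12 and 1 over the list alone). The count of 11 was 8 without KO replicate 1 or 3, 9 without KO replicate 4 and 10 without KO replicate 2. Folr2, Pf4, Tmem119 and Ccl12 of this list were not among the measured genes. Apart from Apoe and Selenop, these markers were at low levels. The complement gene C1qb rose from 7.06 ± 3.16 to 26.2 ± 15 and C3ar1 from 2.01 ± 0.408 to 11.5 ± 3.1. Camera gave an adjusted p of 0.0047 for this list, and 0.866 with an estimated correlation. Monocyte markers went both ways, with 4 of 14 higher and 4 lower (the same over the list alone; 7 lower under the replicate block). The integrin Itgam rose from 13.4 ± 2.5 to 79.1 ± 14.3 and fibronectin Fn1 fell from 757 ± 39.4 to 263 ± 64.7. The monocyte list's median was -0.21 and its mean 0.0217 (camera adjusted p = 0.789).

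Camera called no other marker list. Of 7 neutrophil markers 1 rose and 3 fell (1 and 3 over the list alone; camera adjusted p = 0.395): Cxcr2 rose from 13.3 ± 3.33 to 75.1 ± 16.4 and Csf3r fell from 56.1 ± 3.77 to 18.8 ± 3.91. The other lower neutrophil markers, S100a9 and Mmp9, lost their call without KO replicate 1 (adjusted p = 0.0671 and 0.104), KO replicate 2 (adjusted p = 0.0743 and 0.0819), KO replicate 4 (adjusted p = 0.0528 and 0.0696), WT replicate 1 (adjusted p = 0.0673 and 0.09) or WT replicate 3 (adjusted p = 0.0532 and 0.0657), which left 1 lower neutrophil marker each time. Of 14 dendritic cell markers 2 rose (adjusted p = 0.378), of 3 B cell markers 1 rose, and 2 without WT replicate 3 (0.471), and of 3 T and NK cell markers 2 rose and 1 fell (0.363 by camera, 0.00374, upward, by fry), each with the same counts over the list alone. The 1 measured eosinophil and basophil marker, Gata2, was at 2.05 ± 1 in WT and 2.08 ± 0.599 in KO. In the epithelial list 1 of 15 rose and 1, Epcam, fell, and 2 rose without KO replicate 2 or 4, under the replicate block and under median centring (0.471). Of 11 endothelial markers 1, Vwf, rose, and 2 rose under the replicate block and without KO replicate 4 (adjusted p = 0.395). Of 10 fibroblast and muscle markers 1, Acta2, rose (0.444), and of 4 red blood cell markers 0 passed (0.919). These 4 lists had the same counts over the list alone. WT replicate 3 held the highest WT values of several of these markers, such as Pecam1 at 25.6 against 6.38 to 7.58 in the other WT pools. Without that pool 7 endothelial, 5 fibroblast and 5 epithelial markers were higher in KO, and camera called the endothelial list (adjusted p = 0.00296) and the fibroblast list (adjusted p = 0.00613).

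Among 20 genes that respond to tissue dissociation 2 rose and 0 fell (1 and 0 over the list alone; camera adjusted p = 0.682). These were the heat shock genes Hspa1a, at 3.41 ± 3.29 in WT and 17.8 ± 9.78 in KO, and Hspa1b, which lost its call without KO replicate 4 (adjusted p = 0.054) or without WT replicate 1, 2 or 3 (adjusted p = 0.055, 0.0633 and 0.056). With the replicate number as a block 5 rose and 12 fell, against 1 lower without KO replicate 4 and 2 lower without WT replicate 2. The list's median was -0.36.

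Across the transcriptome, limma tested 12163 genes and called 4708 of them (38.7%) at an adjusted p under 0.05, 2279 higher and 2429 lower in KO. Under median centring 2475 were higher and 2175 lower, so that which direction held more genes depended on the scaling. At least 2-fold changes on this scale were found in 686 genes, 338 higher and 348 lower. The values of the groups did not overlap in 37.7% of genes, against 2.86% by chance, and the median log2 fold change of all genes was -0.0063. Outside the lists, the genes with the highest fold changes among well-expressed genes were Fstl1, a secreted glycoprotein, from 8.34 ± 4.13 to 307 ± 93.4 (log2 fold change 5.08, SE 0.306, limma adjusted p = 3.27e-06), the chemokine receptor Cxcr1 (3.60), the prostacyclin receptor Ptgir (3.46), the aquaglyceroporin Aqp9 (3.42), the milk fat globule protein Mfge8 (3.24), Ceacam1 (2.99), the myosin Myo5a (2.79), Wfdc17 (2.75) and Mreg (2.74). At the other end stood mitochondrial mRNAs, Fabp1 and Ear1, and Txnip, which restrains glucose uptake and thioredoxin, fell from 986 ± 259 to 134 ± 35.4 (log2 fold change -2.87).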

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

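The tests of mt-Co3 and of the interstitial macrophage markers were chosen after the results were seen, and those of the ribosomal proteins were set before their outcome was known. A library was set aside for a closer look where it lay far from the other 3 of its group (by the ratio of the gap to the range). This held 18 times in 328 groups, and chance gives 16.4, about 1 in 20.

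Of these, 5 were in WT replicate 4, 4 in KO replicate 4 and 5 in WT replicate 3. WT replicate 4 was lowest for Sdhb (64.5 against 77.1 to 79.2), Atp5g3 (198 against 231 to 236), Gpnmb (285 against 424 to 455) and Ctsl (229 against 242 to 244), and highest for Polg2 (5.75 against 4.48 to 4.55). KO replicate 4 was lowest for Lonp1 (58 against 74.6 to 77.6), Gpnmb (1528 against 1893 to 1901), Ifi203 (6.27 against 8.73 to 9.09) and Ighm (3.01 against 3.96 to 4.04). WT replicate 3 was highest for Cldn5 (7.18 against 1.99 to 2.12), Pecam1 (25.6 against 6.38 to 7.58), Mgp (10.8 against 2.25 to 2.9), Hba-a2 (6.76 against 2.48 to 2.69) and Hbb-bt (5.58 against 2.22 to 2.27). The others were mt-Co2 in WT replicate 2 (1050 against 1575 to 1703), Smpdl3a in KO replicate 2 (475 against 515 to 522), Acads in WT replicate 1 (80.4 against 72.5 to 73.2) and Psap in KO replicate 1 (13290 against 11740 to 11940). Among the 204 rows under the minimum value, 25 were higher in every KO library than in any WT library and 14 were lower, against 2.9 by chance each way. They include Dcstamp, at 0.0548 to 0.4 in WT and 0.934 to 1.82 in KO, and Elovl3, at 0.283 to 0.533 in WT and 0.62 to 4.34 in KO. Among the tested genes the groups did not overlap in 37.7%, a larger share, so the excess over chance is not particular to the left-out rows.

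Mt-Co3 was listed at 0 reads in 3 of 4 KO libraries while the other mitochondrial mRNAs kept reads there. Reads shared with nuclear copies of mitochondrial DNA are a candidate explanation. The pseudogene Gm28437 on chromosome 1 (24613189 to 24613971, GRCm38) holds 99.9% of the 31-base words of mt-Co3. Summed with it, mt-Co3 had a log2 fold change of -3.88, inside the -4.04 to -3.2 of the other 12 mRNAs treated alike, and 73.1 to 136 in the KO pools. The processing notes name RSEM 1.3.1, but the aligner, annotation and settings behind the division of reads between the copies are not given. A listed 0 therefore need not mean that no read came from mt-Co3.

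All 75 cytosolic ribosomal protein genes were higher in KO, by a median of 0.74 (SE 0.0226, taken over the genes and not over the pools). These genes moved together, with an estimated correlation of 0.802, so this SE does not measure the spread between pools. A trend on transcript length and GC content left a median of 0.71 after it was subtracted, and nuclear respiratory chain genes of similar length (median 607 against 632 bases) had a median of 0.0797. Rescaling the libraries left at least 0.68, with 0.682 under quantile normalisation and 0.762 under median centring. The median of all genes was already -0.0063, so median centring could not have brought the ribosomal median near 0. It shows only that the rise was not a common shift of all genes. Reads moved from pseudogenes would lower the pseudogenes, but 22 measured ribosomal protein pseudogenes had a median of 0.5 (SE 0.218, taken over the pseudogenes). Of these, 6 were called higher and 1 lower. The counting can split reads between a gene and its copies, so a rise of the genes could raise the copies too. The pseudogene values therefore cannot exclude moved reads. Among what stays open are a response to the genotype, which may be biological, and a difference in RNA quality or cell state between the sorted cells, which was not tested.

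Interstitial macrophage markers were higher in KO, and a larger share of interstitial macrophages among the sorted cells could account for it, since the gate used CD45, F4/80 and CD11c and no Siglec-F. Of the 15 measured markers 13 had a WT mean under 10, while Apoe and Selenop stood at 74.8 and 791 in WT. The fold changes of these 13 were taken here on log2(value + 0.25), on which C3ar1 stood at 2.37. On log2(value + 1) C3ar1 stood at 2.04. By the rule written first, an interquartile range of the 13 log2 fold changes above 0.5 or a falling class II gene spoke against a larger share: the range was 1.08 (median SE 0.339) and H2-DMa fell, so that rule excluded it. The class II genes went both ways, however, with 4 of 12 higher and 4 lower. The rule was then rewritten 2 times with the outcome in view, first to a count of markers (13 of 13 higher, from 0.114 to 2.37). By that rule a larger share was favoured, but the count repeats the pattern in question. A change within alveolar macrophages would give the same count. The second rewrite was a rule that needs both, on the ground that an added share gives like folds only where baselines are alike. Because the answer changed with the rule, an added share and a change within alveolar macrophages are left as not told apart here.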

How the results depend on the processing

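The 3 alternatives added after seeing the data were values without a further pseudocount, voom weights and leaving out both replicate-4 libraries. The count of 4708 called genes stayed within 1.5 times under no filter (4735), a minimum of 8 (4030), pseudocounts of 0.25 (4697) and 5 (4704), quantile normalisation (4684, of which 4434 were shared and 1 was called in the opposite direction), median centring (4650, 2475 higher and 2175 lower), no variance trend (4590) and quality weights (5623), and from 3876 (without KO replicate 3) to 4760 (without KO replicate 4) with 1 library left out. Voom weights called 4655, of which 4622 were shared, and 4975 were called without both replicate-4 libraries, 4313 of them shared. By construction, an adjusted p under 0.01 called 3056 (1513 higher, 1543 lower) and a change of at least 1 log2 unit 686 (338 higher, 348 lower). Camera with an estimated correlation called 0 lists in place of 9. In those 9 lists the estimate ran from 0.0804 (interferon-stimulated genes) to 0.802 (cytosolic ribosomal proteins), above the preset 0.01. The adjusted p-values of camera with the preset thus rest on a lower correlation than was estimated here. Other causes were not tested. Tfam had log2 fold changes of -1.92 (pseudocount 5) to -2.81, always called. Of 35 splits of the 8 libraries only the real one, 1, called as many, and the highest other split called 1 gene. Every other split mixes the genotypes, and the difference between genotypes then widens the spread within its groups. Only 8 splits part all 4 same-numbered pairs, too few to reach a share under 0.05. The splits therefore could not exclude an accidental division of the libraries.

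With the replicate number as a block, the paired fit called 5682 genes, 2730 higher and 2952 lower, 4662 of them shared with the unblocked fit. Sex mix differed within the pairs, and the block does not adjust for it. The block called Egr2, Cdh1, Calcrl and Dnajb1 (adjusted p = 0.00132, 0.00139, 0.000346 and 0.0142) and changed no other call of a gene under the naming rule and no list call.

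Of 3608 comparisons of 165 named genes 3419 kept direction and side of the threshold, and of 570 comparisons of 38 lists 535 did. The values or directions that changed sign were of genes and lists that were not called in either fit, and the cause was not tested. Sdha was at -0.044 and Gata2 at -0.030 under quantile normalisation, Hba-a1 at -0.018 with voom weights. Without both replicate-4 libraries, Gata2 was at -0.078, Hba-a1 at -0.25, and camera's sign changed for class II (median 0.238) and dissociation genes (median -0.364). With 1 library left out, changed values ran from -0.0099 to -0.0034 for Sdha, were -0.0020 for Sdhc, -0.069 to -0.011 for Gata2, -0.26 to -0.044 for Hba-a1, 0.017 to 0.091 for Hba-a2, 0.018 to 0.29 for Hbb-bs and 0.076 to 0.26 for Hbb-bt. For lists it was camera's direction that changed, and the medians in those fits were 0.015 to 0.0535 for mitochondrial DNA maintenance, -0.0665 for monocytes, 0.0467 to 0.273 for red blood cells and -0.262 to -0.115 for dissociation genes. With 1 library left out, the extremes farthest from these values were 0.053 for Sdhc, 0.40 for Hba-a1, -0.60 for Hba-a2, -0.46 for Hbb-bs, -0.40 for Hbb-bt, and for lists 0.0874 (mitochondrial DNA maintenance), -0.352 (monocytes), -0.427 (red blood cells) and -0.666 (dissociation genes).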

Other observations

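The patterns here were chosen after their values were seen and were not set as tests. Beyond the listed groups, single genes with large changes included the following. Igf1, a growth factor, rose from 14.4 ± 5.75 to 83 ± 16.6 (mean ± SD of 4 pools, log2 fold change 2.52, limma adjusted p = 0.000113). The receptor Cd93 rose from 71.3 ± 16.2 to 390 ± 46.9, and the scaffold gene Ahnak2 from 34.1 ± 7.91 to 197 ± 30.1. Among genes that fell were the complement receptor C5ar1, from 265 ± 26.2 to 51.2 ± 15.6, Cpne5, from 96.5 ± 6.72 to 13.6 ± 1.66 (log2 fold change -2.74, limma adjusted p = 1.55e-07), the peroxisomal thiolase Acaa1b, from 316 ± 61.9 to 84.6 ± 10.7, and the tight junction gene Cldn1, from 121 ± 10.8 to 31.6 ± 12.8. Some related genes moved in different directions. The chemokine receptors Cxcr1 and Cxcr2 rose, while Csf3r, on the neutrophil marker list with Cxcr2, fell. Ear1 and Ear2 fell while Ear6 rose, though reads can be shared between genes of this family.

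Over all tested genes, KO replicate 4 had the lowest slope of response, though not for every gene. Regressed on the mean change of the other 3 KO pools, its fold changes had a slope of 0.811, against 0.987, 1.01 and 0.991 for KO replicates 1, 2 and 3. With each KO pool taken against the WT pool of its own number, the slope was 0.816, against 0.955, 1.01 and 0.911. Within these pairs the ratio of KO to WT was nevertheless highest in replicate 4 for Gpnmb, Slc7a11, Cxcr1 and Cxcr2. Sex mix also differed within the pairs, and its part in these slopes and ratios was not tested. Library quality weights were lowest for WT replicate 4 (0.403) and KO replicate 4 (0.469). The labels do not say whether these pools were sorted on the same day.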
